A study of Mus musculus with 8 samples.

How the data were processed

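The data were single-cell transcriptomes of lineage-depleted (Lin-) femur bone marrow cells from Ldlr-/- mice, which lack the low-density lipoprotein receptor and are used to study atherosclerosis. Per the labels' protocols, cells carrying CD11b, a surface protein of mature myeloid cells, were removed with magnetic beads before lineage depletion, and the remaining cells were fixed. Cells were barcoded by split-pool combinatorial indexing, in which each fixed cell collects its barcode over successive plates of wells, with 12500 cells per mouse projected and 8 sublibraries made at the end. Each of the 8 sublibraries, which are the 8 samples of the series, mixes cells of all mice and both diets, so the sublibraries are technical parts of 1 mixed group and were not compared as replicates.

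Base calls were demultiplexed with bcl2fastq 2.20.0.422, per the submitters' processing notes. These notes name the mouse build mm10, while the genome column of the deposited gene table names mm39. The 2 sources differ, so no coordinates were taken from either and genes were used by the symbols and identifiers of the deposited gene table. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes could not be separated further. The authors deposited an unfiltered matrix of transcript counts, whole numbers per gene and barcode with no scaling, for 57010 genes and 2057938 barcodes. A deposited cell table gave for each barcode the name of its cell suspension, its sublibrary and its transcript count, and deposited loading and plate sheets gave the diet and mouse number of each suspension and its wells.

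Mice were mapped from the names in the cell table, which carry the diet and a mouse number, and were checked against the loading and plate sheets, where each mouse filled 3 wells of the first plate. The cell table held 10 such names for the 8 mice, because mouse 3 of each diet had a pair of names for 1 loaded suspension. Each pair was summed and counted as 1 mouse. Another 8 names in the cell table, with 339371 barcodes, matched none of the labels and were not used. The mouse was the replicate, with 4 mice per diet, and cells were never treated as replicates.

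Barcodes were kept with at least 500 genes and at most 15% mitochondrial transcripts. Doublets were called per sublibrary with Scrublet as supplied in scanpy 1.11.5, at an expected rate of 0.06, and removed. The called share per mouse ran from 3.63% in HFD-exposed mouse 2 to 10.4% in HFD-exposed mouse 4. These filters left 67924 cells, from 5509 in non-exposed mouse 3 to 13112 in HFD-exposed mouse 4, and total counts per mouse from 50011387 to 175668376. No cell type annotation by the authors was used here. Cells were clustered from 2000 variable genes, 30 principal components and a graph of 15 neighbours with the Leiden method (igraph 0.11.9) at resolution 1, which gave 30 clusters. A cluster took the name of 1 of 19 marker lists if at least 3 of the list's markers were raised by at least 0.585 on the log2 scale over the other cells in at least 5% of its cells. The mean for the second list also had to lie at least 0.2 lower, no other list could have more markers among the leading 10 genes, and the cluster needed at least 50 cells. The numerical limits of this rule were set after the data were seen. Clusters 11 and 28 stayed unnamed. Clusters of 1 name were joined into a class, and class names are used here in the sense of cells like the named type.

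Counts were summed per mouse over all kept cells and over each class in which every mouse had at least 30 cells, which gave 11 sets of sums. The sums were tested between diets with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling and the filterByExpr filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as CPM, counts scaled to a common library size per mouse with TMM factors, and fold changes are log2 of HFD-exposed over non-exposed. Of 28 gene lists, those with at least 5 tested members were tested with camera of limma 3.58.1, at a preset inter-gene correlation of 0.01. The lists were also tested with an estimated correlation and with fry, and by a score, the mean log2 CPM of the members per mouse centred over mice. Scores and class shares were compared with a two-sided exact permutation test over the 70 assignments of the 8 mice, whose smallest possible p is 0.0286. The diet effect was compared between classes in 1 edgeR model with a term per mouse, the class and the interaction of class and diet.

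The rule for naming genes takes, per comparison, up to 10 genes of the largest change among those with an adjusted p under 0.05, at least 10 CPM on average and no overlap between diets, and up to 15 called members of the fixed lists by smallest p. Where fewer than 5 genes passed, the 10 genes of smallest p were given as values. In the sums over all cells and over the early neutrophil class, 14 genes of interleukin 1 signalling, granule formation and neutrophil maturation, with Ldlr, were always reported. List examples are the members of smallest p.

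The procedures were tested on simulated counts with 200 changed genes, each gene's mean level over the mice and the library sizes of the real mice. Genes were drawn independently, without differences between mice that many genes share, so the recovered shares and false calls may differ in the real data. In the early neutrophil class, with 12283 genes, 29.9% of genes changed by 0.5 on the log2 scale were recovered, 82.1% of those changed by 1 and 97.0% of those changed by 2, with 9 unchanged genes called. In the sum over all cells, with 20386 genes, the shares were 2.99%, 37.3% and 78.8%. For the comparison of effects between classes they were 7.46%, 64.2% and 97.0%, simulated on the 10647 genes tested in both classes, fewer than the 12102 genes of the real comparison. The 2 classes were simulated without a mouse effect shared between them, so these shares may differ from those of the real comparison, which has a term per mouse.

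The marker lists, the gene lists, the tests, the rule for naming genes and most alternatives were chosen before the data were examined. These alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom, each mouse left out, the mouse number as a block, at least 300 or 1000 genes per cell, at most 5% mitochondrial transcripts, doublets kept, equal cells per mouse, parts of the sublibraries, Leiden resolutions 0.5 and 2, and other denominators for shares. Chosen after seeing the data were the runs without non-exposed mouse 3 and HFD-exposed mouse 4 together, the runs on single clusters of the early neutrophil and stromal-like classes, and the exact test of list scores. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.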

Results

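The transcriptomes of 67924 lineage-depleted femur bone marrow cells were compared between Ldlr-/- mice exposed to a high-fat diet (HFD, 4 mice) and Ldlr-/- mice not exposed to it (4 mice). The series title places the comparison in atherosclerosis under an alternating HFD and asks about a reprogramming of neutrophil progenitors that depends on interleukin 1 beta. Non-exposed mice 1 to 4 gave 8986, 8994, 5509 and 9270 kept cells, and HFD-exposed mice 1 to 4 gave 7939, 5827, 8287 and 13112. Their total transcript counts in these cells were 106740965, 138005123, 104552868 and 92146281 in the non-exposed mice and 93245126, 50011387, 83711355 and 175668376 in the HFD-exposed mice. The median transcript count per cell was 8094.5, 11343.5, 16194 and 8110.5 in the non-exposed mice and 9675, 5927, 7821 and 11266.5 in the HFD-exposed mice. The loaded suspension of HFD-exposed mouse 4 held 1400 cells per microlitre, against 437 to 729 in the other mice. The 8 sublibraries each held cells of all 8 mice and between 7604 and 9300 kept cells, so they did not separate the diets.

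Ldlr, the gene deleted in every mouse, still gave counts. Its level over all cells was 24.7, 21.7, 24.4 and 26.8 CPM in non-exposed mice 1 to 4 and 19.7, 18.6, 18.5 and 19.9 CPM in HFD-exposed mice 1 to 4. The means were 24.4 ± 2.09 and 19.2 ± 0.728 CPM (SD, n = 4 each), and the log2 fold change of -0.35 ± 0.10 (SE) did not pass the edgeR test (adjusted p = 0.877). Counts of this gene were not divided between the deleted part and the rest of the transcript, so its level does not check the genotype.

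The cells fell into 11 named classes and 2 unnamed clusters, and the erythroid progenitor-like class was the largest. It made up 38.1% ± 6.44 of the kept cells in non-exposed mice and 32.7% ± 8.52 in HFD-exposed mice (SD, n = 4 each, two-sided exact permutation p = 0.314). Cells like granulocyte-monocyte progenitors and early neutrophils (GMP-like), which carry Mpo and Elane, made up 9.96% ± 3.41 and 12.2% ± 5.17 (exact p = 0.543). Their share was 11.7%, 13.2%, 5.36% and 9.57% in non-exposed mice 1 to 4 and 11.01%, 15.5%, 16.8% and 5.34% in HFD-exposed mice 1 to 4. Cells like stem cells and multipotent progenitors (HSC/MPP-like) made up 6.27% ± 1.53 and 6.42% ± 1.60 (exact p = 0.914). Monocyte progenitor-like cells made up 6.21% ± 1.87 and 7.75% ± 3.33 (exact p = 0.429). Stromal and endothelial-like cells, at 0.680% ± 0.325 and 1.13% ± 0.434, gave the smallest p of all classes (exact p = 0.143). They joined cluster 22, led by Cxcl12, Igfbp5 and Kitl, and cluster 27, led by the collagen genes Col1a1 and Col1a2. These clusters were tested apart only after the result was seen. Cluster 27 made up 0.0443% ± 0.0481 and 0.282% ± 0.0857 without overlap between diets (exact p = 0.0286, the smallest possible, adjusted p = 0.857 over the 30 clusters). Cluster 22 made up 0.635% ± 0.286 and 0.847% ± 0.418 (exact p = 0.457). Cluster 27 had 4, 10, 0 and 2 cells in non-exposed mice 1 to 4 and 23, 22, 14 and 38 in HFD-exposed mice 1 to 4. The count of 0 among the 5509 cells of non-exposed mouse 3 allows up to 0.0545%.

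Among the other classes, basophil and mast-like cells made up 6.01% ± 1.49 in non-exposed and 6.07% ± 1.79 in HFD-exposed mice, and megakaryocyte-like cells 11.4% ± 2.51 and 11.2% ± 1.72. Late erythroid-like cells made up 13.9% ± 7.93 and 14.2% ± 7.31, plasma cell-like cells 1.57% ± 0.604 and 1.64% ± 0.742, and T, NK and innate lymphoid-like cells 1.48% ± 0.573 and 1.62% ± 0.741. Cluster 11, unnamed and led by the early lymphoid and stem cell genes Flt3, Dntt, Mecom and Cd34, made up 4.19% ± 0.688 and 4.89% ± 0.967, and cluster 28 made up 0.162% ± 0.0883 and 0.143% ± 0.0602. Granule-stage neutrophil-like cells numbered 94, of which 45 came from HFD-exposed mouse 4, and made up 0.0799% ± 0.0327 and 0.162% ± 0.122 (exact p = 0.2). None of the 13 classes passed the test (exact permutation adjusted p = 0.943 in each). The smallest p that 70 assignments allow is 0.0286, so with 13 classes no adjusted p could pass 0.05 unless at least 8 classes reached it.

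**Figure D1:**
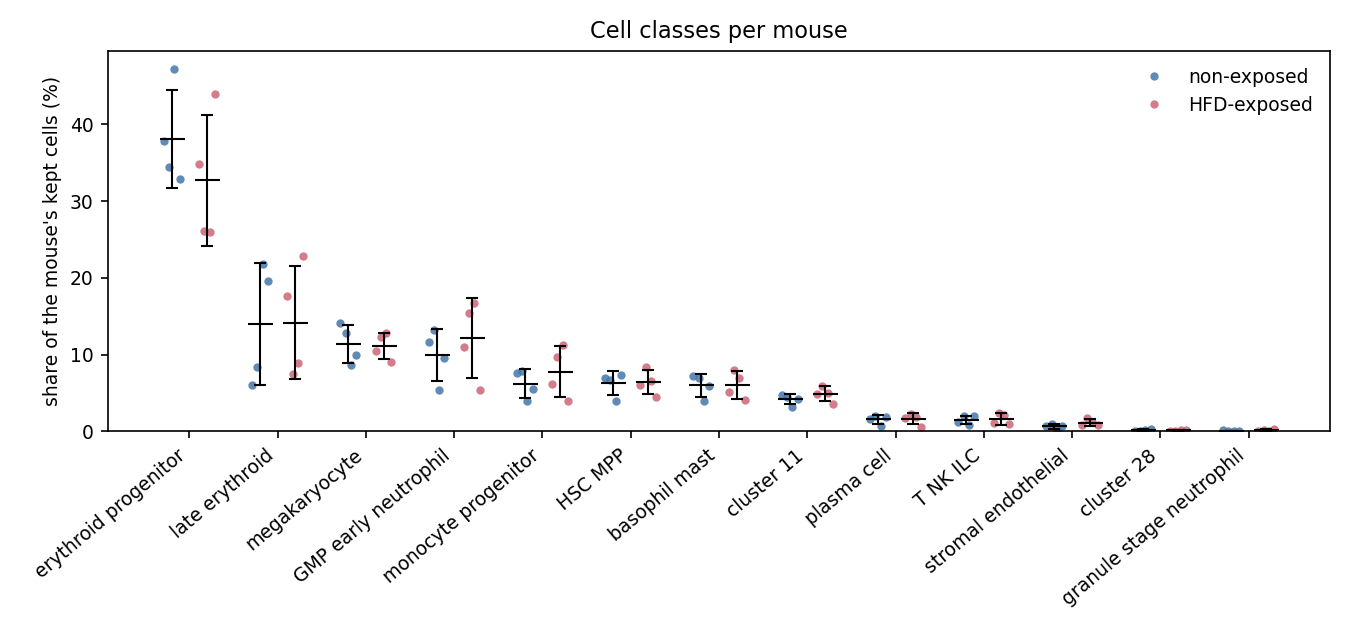
Share of kept cells (%) of each cell class, with 1 point per mouse, a bar and whiskers for the mean and SD over 4 non-exposed and 4 HFD-exposed mice. The GMP-like class ran from 5.36% to 13.2% in non-exposed and from 5.34% to 16.8% in HFD-exposed mice.

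GMP-like cells, the tested class nearest to the neutrophil progenitors of the title, join granulocyte-monocyte progenitors and early neutrophils. Neutrophil progenitors were not separated within this class, and cells carrying CD11b had been removed beforehand. In GMP-like cells 3 genes differed between diets. Ero1b (ENSMUSG00000057069), an oxidase that forms disulfide bonds in the endoplasmic reticulum, fell from 69.9 ± 9.45 to 37.8 ± 3.55 CPM (SD, n = 4 each, log2 fold change -0.88 ± 0.12 SE, adjusted p = 0.0138). Hspa4l (ENSMUSG00000025757), a chaperone of the HSP110 family, fell from 124 ± 4.98 to 78.6 ± 7.53 CPM (-0.66 ± 0.09, adjusted p = 0.0138). Gm48099 (ENSMUSG00000114304), a predicted gene for which reads from near-identical copies could not be separated, rose from 583 ± 153 to 1350 ± 320 CPM (1.21 ± 0.18, adjusted p = 0.0362). Just short of the threshold were Ddit3, a transcription factor of the stress response, at 19.1 ± 3.50 and 9.75 ± 0.702 CPM, Herpud1, which acts in the degradation of misfolded proteins, at 51.1 ± 8.52 and 26.7 ± 5.52 CPM, and Prickle1, of planar cell polarity, at 32.6 ± 4.70 and 53.1 ± 4.41 CPM (adjusted p = 0.0564 each).

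The genes of interleukin 1 signalling and neutrophil maturation did not pass the test in GMP-like cells. Il1r1, the signalling receptor of interleukin 1, stood at 28.4 ± 7.28 CPM in non-exposed and 33.8 ± 6.03 CPM in HFD-exposed mice (log2 fold change 0.24 ± 0.17), and its partner Il1rap at 62.6 ± 6.89 and 66.2 ± 13.8 CPM (0.09 ± 0.14). Csf3r, the receptor of the neutrophil growth factor G-CSF, stood at 201 ± 13.6 and 167 ± 30.2 CPM (-0.27 ± 0.12, adjusted p = 0.741). The granule protein genes Mpo and Elane had fold changes of -0.09 ± 0.10 and 0.11 ± 0.20, and S100a8 of 0.06 ± 0.32. The transcription factors Runx1, Gfi1 and Cebpe gave -0.20 ± 0.10, 0.02 ± 0.19 and -0.04 ± 0.20. The chemokine receptors Cxcr2 and Cxcr4 gave -0.11 ± 0.23 and 0.14 ± 0.16, and Ldlr gave -0.25 ± 0.12. Il1b, with 9 counts over all mice, and Ltf, with 53, lay below the filter on low counts, so a difference was not detectable at this depth.

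These values rest on 12283 genes in 295 to 1390 GMP-like cells per mouse with 3590477 to 12936879 counts, of which 790 genes had an unadjusted p under 0.05 where chance gives 614. DESeq2 called 16 genes, limma voom 3, and edgeR without the filter on low counts 65. The count of 3 became 0 without non-exposed mouse 3 (545 genes at an unadjusted p under 0.05), without HFD-exposed mouse 3 (526) or without HFD-exposed mouse 4 (794), and 7 without non-exposed mouse 1. In the runs without non-exposed mouse 3, HFD-exposed mouse 3 or HFD-exposed mouse 4, in that order, Ero1b had log2 fold changes of -0.85, -0.91 and -0.87. Those of Hspa4l were -0.67, -0.69 and -0.60, and those of Gm48099 were 1.06, 1.21 and 1.05. Without non-exposed mouse 3 and HFD-exposed mouse 4 together, a run chosen after seeing the data, the count was 0 with 504 genes at an unadjusted p under 0.05. With the mouse number as a block it was 0 (565 at an unadjusted p under 0.05), and with doublets kept it was 1. Hspa4l was also not called without non-exposed mouse 2 (adjusted p = 0.0737) or HFD-exposed mouse 1 (adjusted p = 0.0559), and Gm48099 not without non-exposed mouse 4 (adjusted p = 0.0664) or HFD-exposed mouse 1 (adjusted p = 0.0559).

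**Figure D2:**
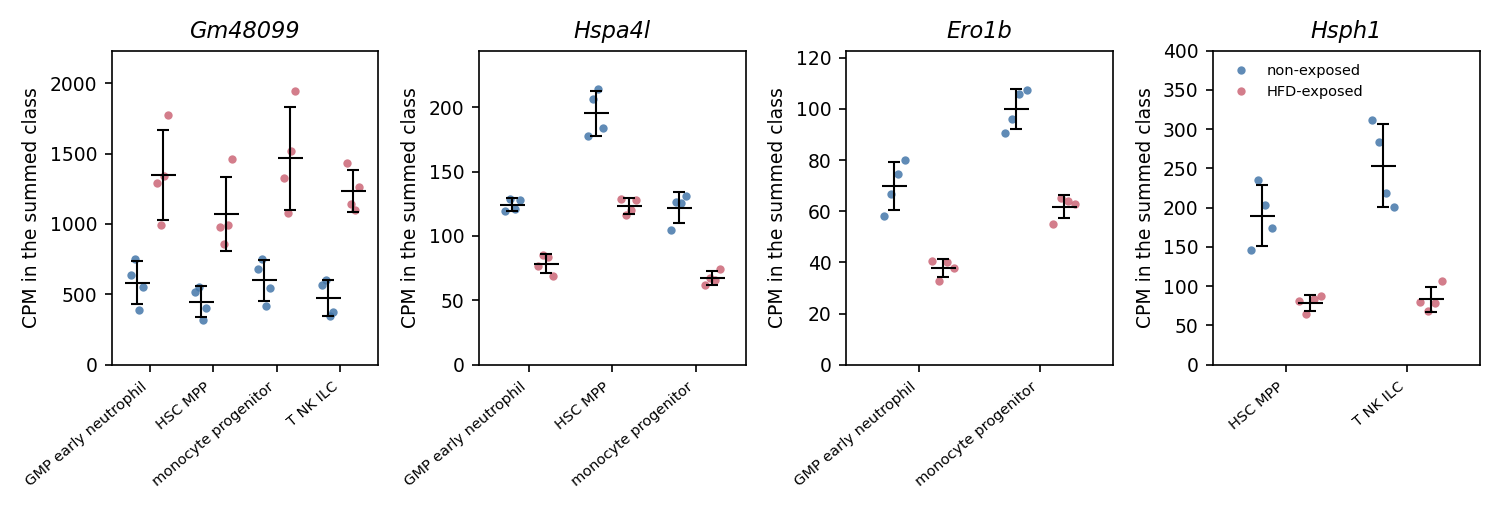
Level (CPM, vertical axis) of Gm48099, Hspa4l, Ero1b and Hsph1 in those of 4 cell classes (horizontal axis) where each was called, with 1 point per mouse and a bar and whiskers for the mean and SD of 4 non-exposed and 4 HFD-exposed mice. In GMP-like cells Ero1b had a mean of 69.9 CPM in non-exposed and 37.8 CPM in HFD-exposed mice.

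Gene lists for the stress of protein folding and for sterol synthesis were lower in GMP-like cells of HFD-exposed mice. Of the cholesterol synthesis list, 21 of 23 tested members had negative fold changes, with a median of -0.29 (camera adjusted p = 6.08e-07, or adjusted p = 0.314 with an estimated correlation). Examples are Hmgcs1, which encodes an early enzyme of the pathway, at 34.5 ± 3.68 and 27.4 ± 1.43 CPM, and Fdps, the farnesyl diphosphate synthase, with -0.57 ± 0.18. No member passed the test over all genes, and 0 passed adjusted over the list alone. Of the list of the unfolded protein response and ATF4, 13 of 14 members were negative, with a median of -0.16 (adjusted p = 1.13e-06, or adjusted p = 0.704 with an estimated correlation). None passed over all genes and 4 did adjusted over the list alone. These were Ddit3, Herpud1, the lumenal chaperone Hspa5 (-0.41 ± 0.14) and the disulfide isomerase Pdia4 (-0.37 ± 0.13). Of the heat shock list, 10 of 11 members were negative, with a median of -0.22 (adjusted p = 6.74e-05, or adjusted p = 0.8289 with an estimated correlation). None passed over all genes and 3 did adjusted over the list alone, which were Hspa1b (-3.39 ± 0.66), Hsph1 (-0.58 ± 0.17) and Chordc1 (-0.36 ± 0.10). Without non-exposed mouse 4 the heat shock list missed the threshold at adjusted p = 0.0579, while the cholesterol and unfolded protein lists kept their call without each of the 8 mice.

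Another 5 of the 26 lists tested in GMP-like cells passed by small amounts. The genes encoded on mitochondrial DNA had positive fold changes in 7 of 7 members (median 0.21, adjusted p = 0.00154), the ribosomal proteins in 26 of 30 (0.07, adjusted p = 0.0105) and the immediate-early genes in 13 of 19 (0.17, adjusted p = 0.0345), each at adjusted p = 0.8289 with an estimated correlation. S phase genes were negative in 18 of 25 members (-0.06, adjusted p = 0.04998) and G2/M genes positive in 19 of 25 (0.10, adjusted p = 0.04997), both at adjusted p = 0.8289 with an estimated correlation. No member of these 5 lists passed over all genes. The mitochondrial list lost its call without non-exposed mouse 3 (adjusted p = 0.130), and the ribosomal list without non-exposed mouse 2 (0.572) or 3 (0.726) or HFD-exposed mouse 2 (0.487) or 4 (0.0504). The immediate-early list lost it without non-exposed mouse 3 (0.308) or 4 (0.637) or HFD-exposed mouse 2 (0.496) or 4 (0.228). The S phase list lost it without non-exposed mouse 2 (0.290), 3 (0.130) or 4 (0.173) or HFD-exposed mouse 1 (0.0616), 3 (0.5002) or 4 (0.0504), and the G2/M list without non-exposed mouse 1 (0.195), 2 (0.537) or 4 (0.0579) or HFD-exposed mouse 1 (0.685) or 4 (0.323). Lists that did not pass were interleukin 1 signalling (14 members, median -0.03, adjusted p = 0.753), NF-kB response (adjusted p = 0.956), interferon response (median 0.13, adjusted p = 0.287), primary granules (median 0.06, adjusted p = 0.786) and secondary and tertiary granules (median -0.05, adjusted p = 0.920).

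In HSC/MPP-like cells, 4 genes fell and 1 rose. Hsph1 (ENSMUSG00000029657), an HSP110 chaperone, fell from 190 ± 38.8 to 79.0 ± 10.1 CPM (SD, n = 4 each, log2 fold change -1.26 ± 0.13 SE, adjusted p = 0.00034). Hspa4l fell from 195 ± 17.5 to 123 ± 6.10 CPM (-0.66 ± 0.09), and Hspa5 (ENSMUSG00000026864), the main chaperone of the endoplasmic reticulum, from 372 ± 22.2 to 238 ± 38.3 CPM (-0.64 ± 0.10, adjusted p = 0.0185). Snca (ENSMUSG00000025889), the alpha-synuclein gene and also a marker of late erythroid cells, fell from 147 ± 38.5 to 59.8 ± 12.6 CPM (-1.28 ± 0.18, adjusted p = 0.00311). Gm48099 rose from 449 ± 108 to 1073 ± 264 CPM (1.25 ± 0.16, adjusted p = 0.00247). The marker list of late erythroid cells, of which Snca is a member, was negative in 6 of 6 members (median -0.19, adjusted p = 0.000346, or adjusted p = 0.334 with an estimated correlation), and that of erythroid progenitors in 12 of 16 (-0.08, adjusted p = 0.00237, or adjusted p = 0.476 with an estimated correlation).

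Of the lists in HSC/MPP-like cells, the heat shock list was negative in 10 of 10 members, with a median of -0.40 (camera adjusted p = 9.49e-19, and adjusted p = 0.0172 with an estimated correlation). Hsph1 passed over all genes and 6 members passed adjusted over the list alone, among them the cytosolic chaperone Hsp90aa1 with -0.45 ± 0.09 and Chordc1 with -0.55 ± 0.12. The cholesterol synthesis list was negative in 20 of 21 members, with a median of -0.26 (adjusted p = 9.34e-07, and adjusted p = 0.0907 with an estimated correlation). Cyp51, a sterol demethylase, stood at 27.2 and 17.9 CPM, and 0 members passed over all genes or adjusted over the list alone. The unfolded protein list was negative in 10 of 13 members, with a median of -0.17 (adjusted p = 0.000124, and adjusted p = 0.147 with an estimated correlation). Hspa5 passed over all genes and 3 members did adjusted over the list alone. The mitochondrially encoded and immediate-early lists were positive in 7 of 7 and 14 of 18 members (adjusted p = 0.0366 and 0.0428, or adjusted p = 0.922 each with an estimated correlation).

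The HSC/MPP-like test covered 10854 genes in 221 to 686 cells per mouse with 1713697 to 3766661 counts, of which 690 genes had an unadjusted p under 0.05 where chance gives 543. DESeq2 called 17 genes, limma voom 5 and edgeR without the filter 65, and the count was 8 without non-exposed mouse 1. At Leiden resolution 0.5 the name covered a different and smaller set of 267 cells, 19 to 55 per mouse, in which 1 gene was called. Hspa5 was not called without non-exposed mouse 2 (adjusted p = 0.0971), HFD-exposed mouse 2 (0.102) or HFD-exposed mouse 3 (0.0841). The count of 5 lists of 24 tested became 3 without non-exposed mouse 3 and 3 without HFD-exposed mouse 3. The mitochondrially encoded list lost its call without non-exposed mouse 2 (0.0622), 3 (0.505) or 4 (0.202) or HFD-exposed mouse 2 (0.127), 3 (0.0753) or 4 (0.0724). The immediate-early list lost its call without non-exposed mouse 3 (0.954) or HFD-exposed mouse 1 (0.205), 2 (0.0620) or 3 (0.0753).

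Whether the diet acted differently in GMP-like and HSC/MPP-like cells was tested as an interaction, and no gene passed. The 3 genes of smallest p, each at adjusted p = 0.0779, were Ero1b, Hsph1 and Snca. For Ero1b the log2 fold change was -0.88 in GMP-like and -0.04 in HSC/MPP-like cells, a difference of -0.84 ± 0.15 (SE). For Hsph1 it was -0.58 and -1.26, a difference of 0.67 ± 0.12, and for Snca -0.14 and -1.28, a difference of 1.14 ± 0.21. Of the lists, the heat shock list differed (median difference 0.31, camera adjusted p = 1.02e-09, or adjusted p = 0.319 with an estimated correlation), as did the G2/M list (0.12, adjusted p = 0.000105, or adjusted p = 0.921 with an estimated correlation) and the ribosomal list (0.08, adjusted p = 3.60e-05, or adjusted p = 0.598 with an estimated correlation). The cholesterol synthesis list did not (adjusted p = 0.671). Beside the 0 genes called by edgeR, 561 of 12102 had an unadjusted p under 0.05 where chance gives 605, and 11 were called without the filter. The count was 2 without non-exposed mouse 1, 1 without non-exposed mouse 4 and 4 without HFD-exposed mouse 4, and no other tool was run on this interaction.

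Monocyte progenitor-like cells, which share the myeloid branch with GMP-like cells, had 4 genes that fell and 1 that rose. Sec24d (ENSMUSG00000039234), part of the coat of vesicles leaving the endoplasmic reticulum, fell from 93.8 ± 9.87 to 48.2 ± 4.57 CPM (SD, n = 4 each, log2 fold change -0.96 ± 0.11 SE, adjusted p = 0.00369). Hspa4l fell from 122 ± 11.7 to 67.4 ± 5.27 CPM (-0.86 ± 0.10, adjusted p = 0.00369), and Ero1b from 99.9 ± 7.91 to 61.8 ± 4.59 CPM (-0.69 ± 0.10, adjusted p = 0.0146). Gm10069 (ENSMUSG00000059659), a predicted gene, fell from 10.1 ± 0.360 to 3.11 ± 0.607 CPM (-1.70 ± 0.22, adjusted p = 0.00589), and Gm48099 rose by 1.29 ± 0.18 (adjusted p = 0.0128). The MHC class II list was negative in 6 of 7 members, with a median of -0.75 (adjusted p = 9.65e-06, or adjusted p = 0.197 with an estimated correlation). No member passed over all genes and 2 did adjusted over the list alone, H2-Ab1 at 6.47 and 3.12 CPM and Cd74, the invariant chain, at 13.9 and 7.10 CPM. Markers of conventional dendritic cells (median -0.47) and of mature B cells (-0.69), which carry the same genes, were lower beside them (adjusted p = 0.00582 each, or adjusted p = 0.135 each with an estimated correlation).

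The heat shock list was negative in 9 of 11 members in monocyte progenitor-like cells (median -0.38, adjusted p = 9.70e-07, or adjusted p = 0.6003 with an estimated correlation), with 5 members passing adjusted over the list alone. The unfolded protein list (median -0.21, adjusted p = 0.00548) and the cholesterol list (-0.10, adjusted p = 0.0148) were also lower, and the mitochondrially encoded list higher (0.24, adjusted p = 0.0113). With an estimated correlation the unfolded protein and cholesterol lists had adjusted p = 0.6003 and the mitochondrial list adjusted p = 0.712 with an estimated correlation. The unfolded protein list lost its call without non-exposed mouse 2 (0.0937) or HFD-exposed mouse 2 (0.0780) or 4 (0.0793), and the cholesterol list without non-exposed mouse 2 (0.0723) or 4 (0.229) or HFD-exposed mouse 2 (0.196). The mitochondrial list lost its call without non-exposed mouse 3 (0.275) or 4 (0.0743) or HFD-exposed mouse 2 (0.0719) or 3 (0.134). The count of 5 genes among 11367 tested (848 at an unadjusted p under 0.05, DESeq2 13) was 3 without non-exposed mouse 4, 2 without HFD-exposed mouse 3 and 0 without non-exposed mouse 3 and HFD-exposed mouse 4 together (673 at an unadjusted p under 0.05). Ero1b was not called without non-exposed mouse 2 (0.0603), 3 (0.0942) or 4 (0.0678) or HFD-exposed mouse 1 (0.0643), 3 (0.0789) or 4 (0.0598). Gm48099 was not called without non-exposed mouse 4 (0.0678) or HFD-exposed mouse 3 (0.0773), and Gm10069 not without HFD-exposed mouse 3 (0.0522).

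In the other classes the called genes were chaperones, predicted genes and an antibody segment. Hsph1 fell in T, NK and innate lymphoid-like cells from 254 ± 52.7 to 83.4 ± 16.2 CPM (SD, n = 4 each, log2 fold change -1.61 ± 0.22 SE, adjusted p = 0.00322). Hspa5 fell in basophil and mast-like cells from 1288 ± 76.5 to 866 ± 75.7 CPM (-0.57 ± 0.09, adjusted p = 0.0125), and Hspa4l in megakaryocyte-like cells from 193 ± 17.8 to 112 ± 4.35 CPM (-0.78 ± 0.08, adjusted p = 0.00786). Gm48099 rose by 1.36 ± 0.18 in T, NK and innate lymphoid-like cells, by 1.26 ± 0.17 in basophil and mast-like cells and by 1.22 ± 0.17 in cluster 11. Gm10069 fell from 14.2 ± 3.31 to 3.43 ± 0.472 CPM in megakaryocyte-like cells (-2.04 ± 0.19) and from 7.34 ± 1.12 to 2.21 ± 0.716 CPM in late erythroid-like cells (-1.63 ± 0.21). Plasma cell-like cells numbered only 38 to 183 per mouse. In them Ighv3-8 (ENSMUSG00000076674), a variable segment of the antibody heavy chain from a family of similar segments, fell from 184 ± 98.2 to 1.15 ± 1.75 CPM (-7.08 ± 0.74, adjusted p = 0.00495). Its fold change was -2.24 with doublets kept (adjusted p = 0.9996) and -8.42 without HFD-exposed mouse 3. The gene was not called by limma voom (adjusted p = 0.448) or without HFD-exposed mouse 1 (0.0807).

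These calls amounted to 2 genes in T, NK and innate lymphoid-like, 2 in basophil and mast-like, 1 in cluster 11, 2 in megakaryocyte-like, 1 in late erythroid-like and 1 in plasma cell-like cells. DESeq2 called 2, 4, 7, 92, 38 and 5 genes in these classes in that order. Without the filter on low counts edgeR called 57, 39, 53, 241, 106 and 153. The T, NK and innate lymphoid-like count was 0 with at least 1000 genes per cell (188 genes at an unadjusted p under 0.05), with equal cells per mouse (135) and in sublibraries 1 to 4 (131). It was 1 in sublibraries 5 to 8 and 8 with the mouse number as a block. The basophil and mast-like count was 0 with doublets kept (519 genes at an unadjusted p under 0.05). It was 1 in sublibraries 5 to 8, with the mouse number as a block and without non-exposed mouse 2, HFD-exposed mouse 2 or HFD-exposed mouse 4. The cluster 11 count was 0 without HFD-exposed mouse 1 (662 genes at an unadjusted p under 0.05) or 3 (632), 2 without non-exposed mouse 3 or HFD-exposed mouse 2 and 3 without non-exposed mouse 4. The megakaryocyte-like count was 1 without non-exposed mouse 3 or HFD-exposed mouse 1 or 4, 5 without non-exposed mouse 1 and 8 without non-exposed mouse 4. The late erythroid-like count was 0 without non-exposed mouse 3 (682 genes at an unadjusted p under 0.05), HFD-exposed mouse 3 (728) or HFD-exposed mouse 4 (903) and in sublibraries 5 to 8 (841). It was 6, 4, 14 and 3 without non-exposed mice 1, 2 and 4 and HFD-exposed mouse 1. With the mouse number as a block it was 7, with equal cells per mouse 8 and in sublibraries 1 to 4 it was 11. The plasma cell-like count was 0 without HFD-exposed mouse 1 (418 genes at an unadjusted p under 0.05) and 2 without non-exposed mouse 1 or 4 or HFD-exposed mouse 2, and limma voom called 0 (427). It was also 0 with doublets kept (378), with equal cells per mouse (195) and in sublibraries 1 to 4 (203). Without non-exposed mouse 3 and HFD-exposed mouse 4 together, a run chosen after seeing the data, edgeR called 0 genes in cluster 11 (583 at an unadjusted p under 0.05), late erythroid-like (571), megakaryocyte-like (592) and plasma cell-like cells (446), and 1 in T, NK and innate lymphoid-like cells.

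The heat shock list was lower in each of these classes. In T, NK and innate lymphoid-like cells it was negative in 9 of 9 members with a median of -0.67 (camera adjusted p = 3.95e-14, and adjusted p = 0.00730 with an estimated correlation). Markers of erythroid progenitors were negative there in 9 of 9 members (median -0.68, adjusted p = 0.00131) and those of late erythroid cells in 5 of 5 (-0.13, adjusted p = 0.0483), both at adjusted p = 0.543 with an estimated correlation. In megakaryocyte-like cells it was negative in 12 of 13 members with a median of -0.54 (adjusted p = 8.65e-20, or adjusted p = 0.141 with an estimated correlation), and in late erythroid-like cells in 10 of 10 with -0.38 (adjusted p = 2.80e-16, or adjusted p = 0.0579 with an estimated correlation). Plasma cell-like cells had a median of -0.46 (adjusted p = 3.10e-06, or adjusted p = 0.413 with an estimated correlation), basophil and mast-like cells of -0.27 (adjusted p = 3.94e-06, or adjusted p = 0.240 with an estimated correlation) and cluster 11 of -0.25 (adjusted p = 3.13e-07, or adjusted p = 0.492 with an estimated correlation). Adjusted over the list alone, 6, 7, 7, 3, 5 and 4 members passed in these 6 classes in that order, and over all genes Hsph1 did in T, NK and innate lymphoid-like cells. The cholesterol synthesis list was lower beside it in megakaryocyte-like cells (22 of 23 members negative, median -0.30, adjusted p = 1.93e-12, or adjusted p = 0.141 with an estimated correlation) and in late erythroid-like cells (21 of 22, -0.25, adjusted p = 6.38e-09, or adjusted p = 0.0579 with an estimated correlation). Adjusted over the list alone, 6 and 5 of its members passed there.

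The mitochondrially encoded list, which can also reflect RNA quality, was higher beside the lower heat shock list in 4 of these 6 classes. It was positive in 8 of 8 members in late erythroid-like cells (median 0.28, camera adjusted p = 0.000400, or adjusted p = 0.490 with an estimated correlation) and in 7 of 7 in basophil and mast-like cells (0.23, adjusted p = 0.00195, or adjusted p = 0.489 with an estimated correlation). It was positive in 6 of 7 members in cluster 11 (0.23, adjusted p = 0.0126, or adjusted p = 0.919 with an estimated correlation) and in 8 of 8 in megakaryocyte-like cells (0.26, adjusted p = 0.0164, or adjusted p = 0.844 with an estimated correlation). In T, NK and innate lymphoid-like cells (-0.09, adjusted p = 0.921) and plasma cell-like cells (-0.05, adjusted p = 0.836) it did not pass. The call in basophil and mast-like cells was lost without non-exposed mouse 3 (0.0914), and that in cluster 11 without non-exposed mouse 3 (0.586) or 4 (0.216) or HFD-exposed mouse 2 (0.112) or 3 (0.0980). The call in megakaryocyte-like cells was lost without non-exposed mouse 3 (0.318) or 4 (0.113) or HFD-exposed mouse 2 (0.128) or 3 (0.142), while that in late erythroid-like cells was kept without each of the 8 mice.

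Erythroid progenitor-like cells, the class with the most counts at 15036236 to 94663147 per mouse, gave 0 called genes, while the heat shock list was lower. It was negative in 12 of 12 members with a median of -0.41 (camera adjusted p = 3.39e-20, or adjusted p = 0.146 with an estimated correlation), and 10 members passed adjusted over the list alone. The inducible chaperone Hspa1b stood at 9.09 CPM in non-exposed and 0.707 CPM in HFD-exposed mice (log2 fold change -3.78, adjusted p = 0.0886), and Hspa4l had a fold change of -0.69. The cholesterol synthesis list was negative in 21 of 23 members (median -0.23, adjusted p = 2.89e-11), with 7 passing adjusted over the list alone, and the unfolded protein list in 14 of 15 (-0.29, adjusted p = 2.89e-11), with 4. Both lists had adjusted p = 0.146 with an estimated correlation. The mitochondrially encoded list was positive in 8 of 8 members (median 0.17, adjusted p = 0.0372, or adjusted p = 0.651 with an estimated correlation). Its call was lost without non-exposed mouse 2 (0.0867), 3 (0.395) or 4 (0.135) or HFD-exposed mouse 2 (0.0873) or 3 (0.0808). Markers of stromal and endothelial cells were positive in 6 of 8 members (0.44, adjusted p = 5.56e-05, or adjusted p = 0.755 with an estimated correlation), with 3 members passing adjusted over the list alone. Beside the 0 genes called by edgeR among 15758, 1286 had an unadjusted p under 0.05 where chance gives 788. DESeq2 called 73, limma voom 0 and edgeR without the filter 217, and the count was 3 without non-exposed mouse 1.

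Over all Lin- cells no gene passed the test, and the lists of protein folding and sterol synthesis were lower. This sum holds the cells of the classes above, and all come from the same 8 mice, so it is not an independent observation. The heat shock list was negative in 13 of 13 members with a median of -0.59 (camera adjusted p = 7.46e-20, or adjusted p = 0.0809 with an estimated correlation). Hspa1b had a log2 fold change of -2.78 ± 0.67 (SE, n = 4 each), Bag3, a partner of the HSP70 chaperones, stood at 26.1 and 17.2 CPM and Chordc1 at 135 and 90.1 CPM, and 7 members passed adjusted over the list alone. The cholesterol synthesis list was negative in 23 of 23 members with a median of -0.27 (adjusted p = 1.10e-13, or adjusted p = 0.0809 with an estimated correlation). Hmgcs1 stood at 21.1 ± 1.02 and 16.6 ± 0.520 CPM, Cyp51 had -0.57 ± 0.14 and Msmo1 -0.48 ± 0.12, and 4 members passed adjusted over the list alone. The unfolded protein list was negative in 14 of 16 members with a median of -0.20 (adjusted p = 4.61e-06, or adjusted p = 0.231 with an estimated correlation), with 2 members passing adjusted over the list alone. As scores per mouse, heat shock and cholesterol synthesis each gave an exact permutation p of 0.0286, the smallest that 8 mice allow, and an adjusted p of 0.386 over the lists.

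The gene of smallest p over all cells was Gm10069, at 9.28 ± 1.20 CPM in non-exposed and 3.31 ± 0.373 CPM in HFD-exposed mice (log2 fold change -1.49 ± 0.15 SE, adjusted p = 0.0587). After it came the chloride channel gene Ano1 (1.39 ± 0.19), Entpd3 (2.07 ± 0.35), Gm48099 (1.23 ± 0.21), Hspa4l (-0.74 ± 0.13), Fxyd6 (2.52 ± 0.47), Gnai1 (1.70 ± 0.32), Ptprz1 (1.88 ± 0.35), Hspa1a (-2.99 ± 0.56) and Gli2 (1.58 ± 0.30). None of them passed the test, and Entpd3 lay as low as 0.257 to 0.556 CPM in the non-exposed mice. Il1b stood at 1.54 ± 0.643 and 1.501 ± 0.819 CPM (-0.06 ± 0.42), Il1r1 at 20.4 ± 1.83 and 23.4 ± 1.55 CPM (0.19 ± 0.11) and Il1rap at 35.8 ± 2.81 and 41.6 ± 6.39 CPM (0.21 ± 0.13). The fold changes of Csf3r, Cxcr2, Cxcr4, Runx1, Cebpe and Gfi1 were 0.09 ± 0.36, 0.22 ± 0.33, 0.27 ± 0.22, -0.07 ± 0.12, 0.33 ± 0.33 and 0.46 ± 0.46, and those of the granule genes Mpo, Elane, Ltf and S100a8 were 0.30 ± 0.37, 0.53 ± 0.52, 0.75 ± 0.47 and 0.73 ± 0.39. Secondary and tertiary granule genes were positive in 16 of 18 members (median 0.50, adjusted p = 0.00179, or adjusted p = 0.810 with an estimated correlation), and marker lists of other cell types moved with them. These were granule-stage neutrophils (median 0.55, adjusted p = 6.58e-05, or adjusted p = 0.966 with an estimated correlation), stromal and endothelial cells (0.49, adjusted p = 1.11e-06, or adjusted p = 0.966 with an estimated correlation) and monocyte progenitors (0.37, adjusted p = 0.00166, or adjusted p = 0.994 with an estimated correlation). As scores per mouse these marker lists gave exact permutation p values of 0.2, 0.0857 and 0.514 in that order. The granule-stage marker list shares most of its members with the secondary and tertiary granule list, so its rise is not a separate observation.

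Beside the 0 genes called by edgeR over all Lin- cells, 825 of 20386 had an unadjusted p under 0.05 where chance gives 1019, DESeq2 called 85 and limma voom 0. Myeloid transcription factors (17 of 20 positive, adjusted p = 0.0205), mitochondrially encoded genes (8 of 8, adjusted p = 0.0205) and immediate-early genes (18 of 21, adjusted p = 0.0225) also passed, each at adjusted p = 0.893 with an estimated correlation. The count of 7 lists of 27 became 14 without non-exposed mouse 2, 3 without non-exposed mouse 3, 17 without HFD-exposed mouse 4 and 11 without non-exposed mouse 3 and HFD-exposed mouse 4 together. The granule list lost its call without non-exposed mouse 3 (0.0552) or HFD-exposed mouse 3 (0.112), and the mitochondrial list without non-exposed mouse 2 (0.0809), 3 (0.255) or 4 (0.0863) or HFD-exposed mouse 4 (0.0935). The transcription factor list lost it without non-exposed mouse 3 (0.571) or HFD-exposed mouse 2 (0.182) or 3 (0.428), and the immediate-early list without non-exposed mouse 3 (0.8287) or HFD-exposed mouse 2 (0.354) or 3 (0.130).

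**Figure D3:**
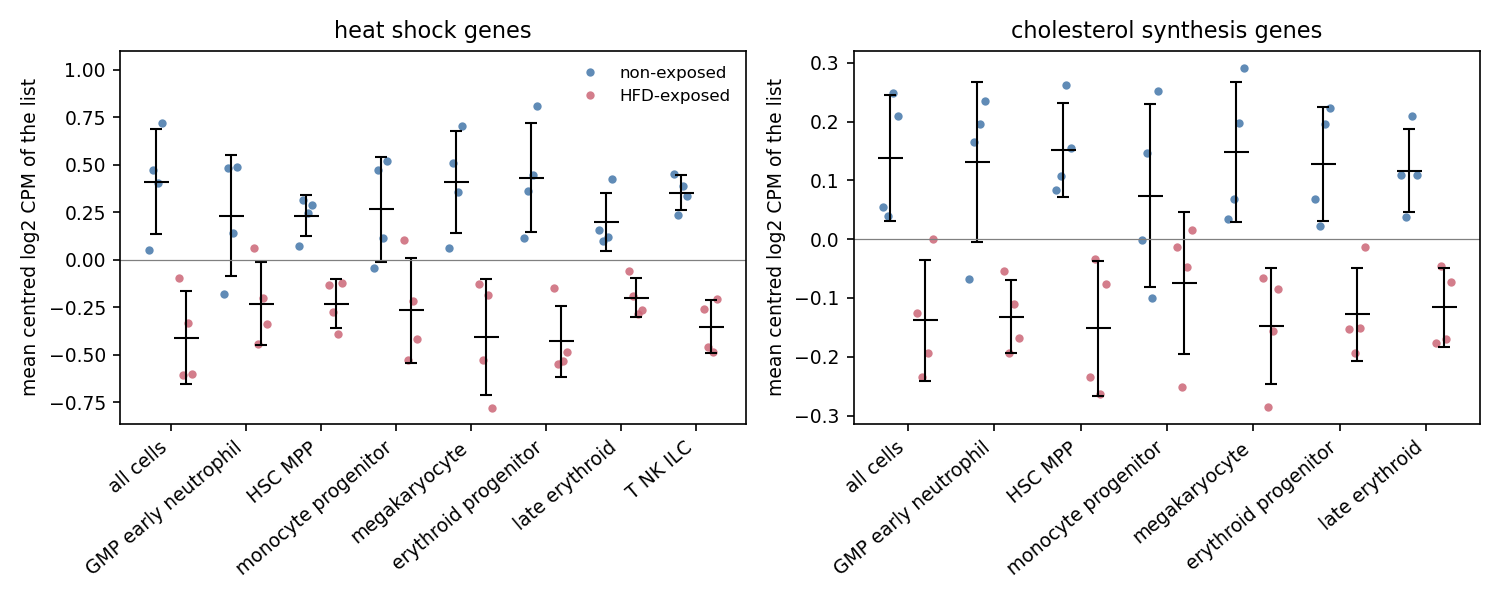
Score of the heat shock and cholesterol synthesis lists (mean log2 CPM of the members per mouse, centred over the 8 mice) in all Lin- cells and the classes on the horizontal axis, with 1 point per mouse and a bar and whiskers for the mean and SD of 4 non-exposed and 4 HFD-exposed mice. Over all cells the heat shock score ran from 0.05 to 0.72 in non-exposed and from -0.61 to -0.10 in HFD-exposed mice.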

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

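The tests of explanations for the heat shock pattern were chosen only after the result was seen, while the comparison of diet effects between classes and the rule for a sample far from its group were chosen before. Of 218 groups of 4 mice examined for a mouse far from the other 3, 9 had one, where chance gives about 5%. HFD-exposed mouse 4 had 7253 barcodes with 300 to 499 genes, against 296 to 361 in the other HFD-exposed mice, and its granule-stage neutrophil-like cells made up 0.343% of the kept cells, against 0.0882% to 0.120%. Non-exposed mouse 3 had 5509 kept cells, against 8986 to 9270, and a score of secondary and tertiary granule genes over all cells of -0.73, against -0.04 to 0.05. Snca in HSC/MPP-like cells stood at 89.8 CPM in non-exposed mouse 1, against 162 to 169 CPM, and at 78.5 CPM in HFD-exposed mouse 4, against 51.8 to 55.3 CPM. Tmem39a, a transmembrane protein gene, stood at 56.1 CPM in monocyte progenitor-like cells of non-exposed mouse 1, against 45.2 to 45.7 CPM. Gm10069 stood at 5.04 CPM in GMP-like cells of HFD-exposed mouse 3, against 3.38 to 3.65 CPM, and Entpd3 at 0.556 CPM over all cells in non-exposed mouse 2, against 0.257 to 0.289 CPM.

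The diet effect on 3 lists differed between GMP-like and HSC/MPP-like cells in the interaction test with a preset correlation. Heat shock genes differed by a median of 0.31 on the log2 scale (adjusted p = 1.02e-09, or adjusted p = 0.319 with an estimated correlation), with the lower fold changes in HSC/MPP-like cells. G2/M genes differed by 0.12 (adjusted p = 0.000105, or adjusted p = 0.921 with an estimated correlation) and ribosomal protein genes by 0.08 (adjusted p = 3.60e-05, or adjusted p = 0.598 with an estimated correlation), both higher in GMP-like cells.

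Heat shock genes were lower in HFD-exposed mice with a preset correlation over all cells (median log2 fold change -0.59, adjusted p = 0.0809 with an estimated correlation) and in the 10 classes tested, of which HSC/MPP-like and T/NK-like cells kept the call at adjusted p = 0.0172 and adjusted p = 0.00730 with an estimated correlation. The classes and the sum over all cells share the same 8 mice, so these calls are not independent of each other. Non-exposed mouse 3, with 5509 kept cells, and HFD-exposed mouse 4, whose loaded suspension held 1400 cells per microlitre, are argued against as the cause. Without both, 92.4% of the difference in score over all cells was left (-0.82 with 8 mice and -0.76 without, with no overlap). RNA carried over from late erythroid-like cells, whose markers were lower in HFD-exposed mice in both classes, is argued against too. It would give a median of 4.85% of the fall in HSC/MPP-like and 9.55% in T/NK-like cells, from marker levels of at most 3.19% and 9.18% of those in late erythroid-like cells. Carry-over from erythroid progenitor-like cells, whose markers were also lower in both classes, was not measured and stays open. A handling response that raises immediate-early and heat shock genes together would lower both in HFD-exposed mice, while the immediate-early score over all cells was higher there by 0.23, and the list was called higher with a preset correlation in 6 classes and lower in late erythroid-like cells, so at an exact permutation p of 0.486 it cannot be told apart from an effect of diet. An effect of the diet on the chaperone system stays open and untested, as does any difference in the time or temperature at which the mice of each diet were processed.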

How the results depend on the processing

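The runs without non-exposed mouse 3 and HFD-exposed mouse 4 together, the runs on single clusters of the GMP-like and stromal-like classes and the exact tests of list scores were tests chosen only after the result was seen, and all others were planned. No called gene reversed its direction under any alternative that was run, and no called list passed the threshold in the opposite direction. Lists that lost their call were not checked for a change of direction. The 60 reversals all concerned class shares, none of which passed the adjusted test with all kept cells. Of these, 1 reversed share, that of basophil/mast-like cells under another denominator, had an unadjusted exact permutation p of 0.0286. Of the values for single genes called between the diets, 399 kept their call and 86 lost it over the alternatives, and of those for lists 514 kept it and 292 lost it. The 292 include every list call under the exact permutation test of list scores, which called 0 lists. With a smallest possible p of 0.0286 in that test, those losses were nearly fixed in advance. Among genes named without a call, 2063 values stayed as they were, 87 moved and 194 passed the threshold. The mouse number did not pair the mice, with correlations across genes, which are not independent replicates, of -0.36, 0.45, -0.40 and 0.08 between mice of 1 number in all cells. The cause was not tested for any of the changes listed here, except that leaving out mice leaves fewer samples, omitting the filter raises the number of genes tested, and smaller parts of the cells lower the depth.

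The difference in class share, HFD-exposed minus non-exposed, changed its sign as follows, in percentage points. With at least 300 genes per cell it was -0.0609 in HSC/MPP-like, -1.14 in late erythroid-like and 0.660 in megakaryocyte-like cells, and with at least 1000 genes -0.185 in T/NK-like, -0.342 in basophil/mast-like, 0.122 in megakaryocyte-like and -0.0341 in plasma cell-like cells. At most 5% mitochondrial counts gave 0.0719 in megakaryocyte-like and Leiden resolution 0.5 gave -0.0570 in HSC/MPP-like cells. Sublibrary 1 alone gave -0.782 in basophil/mast-like, -0.00402 in granule-stage-like and 0.605 in megakaryocyte-like cells. Sublibrary 2 alone gave -0.0708 in HSC/MPP-like, -0.475 in T/NK-like, -0.0525 in basophil/mast-like, 0.0574 in cluster 28 and 0.512 in megakaryocyte-like cells. Sublibrary 3 alone gave -0.131 in HSC/MPP-like, -0.119 in cluster 11, 0.0893 in cluster 28, 0.643 in megakaryocyte-like and -0.497 in plasma cell-like cells. Sublibrary 4 alone gave -0.0532 in plasma cell-like cells, and sublibrary 6 alone -0.586 in late erythroid-like and -0.103 in plasma cell-like cells. Sublibrary 7 alone gave -0.139 in basophil/mast-like, 0.0723 in cluster 28 and -0.250 in late erythroid-like cells. Sublibrary 8 alone gave -0.0852 in HSC/MPP-like, -0.231 in T/NK-like, -0.205 in basophil/mast-like and -0.0151 in granule-stage-like cells. As a share of cells outside the lymphoid, erythroid and stromal classes it was -0.874 in HSC/MPP-like and -1.09 in basophil/mast-like cells (exact permutation p = 0.0286 in the latter). As a centred log2 ratio it was -0.132 in HSC/MPP-like, -0.0713 in T/NK-like, -0.166 in basophil/mast-like, -0.0935 in late erythroid-like and -0.162 in plasma cell-like cells. Without non-exposed mouse 3 and HFD-exposed mouse 4 together it was -0.0255 in late erythroid-like cells.

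Leaving out each mouse in turn gave share differences from 0.646 to 4.46 in GMP-like, -0.612 to 0.768 in HSC/MPP-like, -0.111 to 0.378 in T/NK-like, -0.634 to 0.714 in basophil/mast-like and 0.340 to 1.12 in cluster 11 cells. The ranges were -0.0483 to 0.0237 in cluster 28, -9.09 to -2.31 in erythroid progenitor-like, 0.0217 to 0.107 in granule-stage-like, -2.64 to 2.85 in late erythroid-like and -1.13 to 0.688 in megakaryocyte-like cells. They were 0.382 to 2.81 in monocyte progenitor-like, -0.216 to 0.432 in plasma cell-like and 0.264 to 0.568 in stromal-like cells, where cluster 22 alone gave 0.211 and cluster 27 alone 0.237 (exact permutation p = 0.0286, adjusted p = 0.857 over 30 clusters). The count of called genes ran from 0 to 0 in all cells, 0 to 7 in GMP-like, 4 to 8 in HSC/MPP-like, 2 to 3 in T/NK-like, 1 to 3 in basophil/mast-like, 0 to 3 in cluster 11 and 0 to 3 in erythroid progenitor-like cells. It ran from 0 to 14 in late erythroid-like, 1 to 8 in megakaryocyte-like, 2 to 6 in monocyte progenitor-like and 0 to 2 in plasma cell-like cells, and from 0 to 4 for the difference between classes. The count of called lists ran from 3 to 17 in all cells, 4 to 7 in GMP-like, 3 to 5 in HSC/MPP-like, 4 to 6 in T/NK-like, 4 to 7 in basophil/mast-like, 3 to 6 in cluster 11 and 3 to 11 in erythroid progenitor-like cells. It ran from 5 to 10 in late erythroid-like, 4 to 9 in megakaryocyte-like, 3 to 8 in monocyte progenitor-like and 3 to 5 in plasma cell-like cells.

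Without the filter on low counts edgeR called 1 gene in all cells, 65 in GMP-like, 65 in HSC/MPP-like, 57 in T/NK-like, 39 in basophil/mast-like, 53 in cluster 11, 217 in erythroid progenitor-like, 106 in late erythroid-like, 241 in megakaryocyte-like, 89 in monocyte progenitor-like and 153 in plasma cell-like cells, and 11 for the difference between classes. DESeq2 called 85 in all cells, 16 in GMP-like, 17 in HSC/MPP-like, 4 in basophil/mast-like, 7 in cluster 11, 73 in erythroid progenitor-like, 38 in late erythroid-like, 92 in megakaryocyte-like, 13 in monocyte progenitor-like and 5 in plasma cell-like cells, and limma voom 0 in plasma cell-like cells (427 at an unadjusted p under 0.05). The mouse number as a block gave 0 in GMP-like (565), 8 in T/NK-like, 1 in basophil/mast-like, 7 in late erythroid-like, 2 in monocyte progenitor-like and 2 in plasma cell-like cells. Without non-exposed mouse 3 and HFD-exposed mouse 4 together edgeR called 0 in GMP-like (504 at an unadjusted p under 0.05), 1 in T/NK-like, 0 in cluster 11 (583), 0 in late erythroid-like (571), 0 in megakaryocyte-like (592), 0 in monocyte progenitor-like (673) and 0 in plasma cell-like cells (446). With doublets kept it called 1 in all cells, 1 in GMP-like, 0 in basophil/mast-like (519) and 0 in plasma cell-like cells (378), and with at least 1000 genes per cell 0 in T/NK-like cells (188). Equal cells per mouse gave 5 in GMP-like, 0 in T/NK-like (135), 4 in erythroid progenitor-like, 8 in late erythroid-like and 0 in plasma cell-like cells (195). Sublibraries 1 to 4 gave 6 in GMP-like, 0 in T/NK-like (131), 2 in cluster 11, 2 in erythroid progenitor-like, 11 in late erythroid-like and 0 in plasma cell-like cells (203). Sublibraries 5 to 8 gave 1 in T/NK-like, 1 in basophil/mast-like, 2 in cluster 11, 6 in erythroid progenitor-like, 0 in late erythroid-like (841) and 3 in monocyte progenitor-like cells. Leiden resolution 2 gave 5 in GMP-like and resolution 0.5 gave 1 in HSC/MPP-like cells. At resolution 0.5 that name covered 267 cells, 19 to 55 per mouse, against 4254 cells at resolution 1. Its values there concern a different set that would miss the minimum of 30 cells per mouse.

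With an estimated correlation, camera called 1 list in HSC/MPP-like and 1 in T/NK-like cells, both heat shock, and 0 in all cells, GMP-like, basophil/mast-like, cluster 11, erythroid progenitor-like, late erythroid-like, megakaryocyte-like, monocyte progenitor-like and plasma cell-like cells. With fry the count was 2 in HSC/MPP-like, 1 in T/NK-like and 3 in late erythroid-like cells, and 0 in all cells and the 7 other classes. The exact permutation of the mean log2 CPM of each list gave 0 lists in all cells and in all 10 classes, where 70 assignments allow no smaller p than 0.0286. Without non-exposed mouse 3 and HFD-exposed mouse 4 together the count of lists was 11 in all cells, 4 in GMP-like and 5 in plasma cell-like cells.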

Other observations

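The test of sterol load and the test of ribosomal RNA reads were chosen before their results were seen, except that the median of a wider list of lipid efflux genes and Cdk8 in 1 class had been seen by then. The other tests here, and the genes named for the structure of the samples, were chosen only after the result was seen. Immediate-early genes, which respond within minutes to signals and to handling, moved in opposite directions between classes. They were higher in HFD-exposed mice in plasma cell-like cells (12 of 13 members, median log2 fold change 0.57, camera adjusted p = 3.55e-07, or adjusted p = 0.413 with an estimated correlation), where Klf6 stood at 69.9 and 127 CPM and Fos at 412 and 616 CPM. They were also higher in basophil and mast-like cells (15 of 17, 0.24, adjusted p = 1.05e-05, or adjusted p = 0.484 with an estimated correlation), where 3 members passed adjusted over the list alone, Klf2 (0.64 ± 0.21 SE, n = 4 each), Fos (0.41 ± 0.14) and Dusp1 (0.38). The same held in T, NK and innate lymphoid-like cells (11 of 11, 0.27, adjusted p = 0.000704, or adjusted p = 0.290 with an estimated correlation), where Fosb stood at 675 and 968 CPM, and in megakaryocyte-like cells (16 of 19, 0.25, adjusted p = 0.00104, or adjusted p = 0.249 with an estimated correlation). In late erythroid-like cells they were lower (9 of 12, -0.18, adjusted p = 0.0142, or adjusted p = 0.246 with an estimated correlation), a call lost without non-exposed mouse 4 (adjusted p = 0.0694) or HFD-exposed mouse 2 (adjusted p = 0.0806). Differences between these classes were not tested.

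In T, NK and innate lymphoid-like cells the S phase list was lower in HFD-exposed mice (16 of 17 members negative, median -0.44, adjusted p = 0.000321), as was the G2/M list (11 of 11, -0.32, adjusted p = 0.0108), both at adjusted p = 0.580 with an estimated correlation. Markers of erythroid progenitors were lower beside them (9 of 9 negative, -0.68, adjusted p = 0.00131, or adjusted p = 0.543 with an estimated correlation). The S phase list lost its call without non-exposed mouse 1 (adjusted p = 0.116), and the G2/M list without non-exposed mouse 1 (adjusted p = 0.168), non-exposed mouse 3 (adjusted p = 0.173) or HFD-exposed mouse 2 (adjusted p = 0.210). In cluster 11 the G2/M list was lower (21 of 25 negative, -0.18, adjusted p = 7.01e-05, or adjusted p = 0.919 with an estimated correlation), a call lost without HFD-exposed mouse 2 (adjusted p = 0.0701). In late erythroid-like cells the G2/M list was higher instead (19 of 25 positive, 0.08, adjusted p = 0.0142, or adjusted p = 0.536 with an estimated correlation), a call lost without non-exposed mouse 1 (adjusted p = 0.0565) or 2 (adjusted p = 0.193) or HFD-exposed mouse 1 (adjusted p = 0.110) or 4 (adjusted p = 0.0557). Unfolded protein genes were lower in late erythroid-like cells (14 of 14, -0.30, adjusted p = 1.54e-13, or adjusted p = 0.0579 with an estimated correlation) and in basophil and mast-like cells (12 of 14, -0.21, adjusted p = 7.71e-06, or adjusted p = 0.141 with an estimated correlation). Markers of eosinophils were lower in basophil and mast-like cells (4 of 5, -0.77, adjusted p = 0.000109, or adjusted p = 0.261 with an estimated correlation).

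Cholesterol synthesis genes were lower in HFD-exposed mice over all cells, with a median log2 fold change of -0.27, a call lost at adjusted p = 0.0809 with an estimated correlation. Non-exposed mouse 3 and HFD-exposed mouse 4 are argued against as the cause, since 103% of the difference in score was left without both (-0.28 with 8 mice and -0.29 without, with no overlap). A higher sterol load of the cells, the biological explanation the diet names, would raise the sterol-responsive genes Abca1 and Abcg1, which export sterols, and Mylip, which degrades the LDL receptor. Their mean log2 fold change was 0.13 (exact permutation p = 0.457), with Abca1 at 0.40 ± 0.18 (SE, n = 4 each), Abcg1 at 0.10 and Mylip at -0.10. This cannot be told apart from no change with 4 mice per diet, so this test left a sterol load undecided.

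Gm48099 rose in 6 of the 10 classes tested, which share the same 8 mice, and Mir6236 stood at 2102 and 3914 CPM over all cells (log2 fold change 0.90 ± 0.25 SE, n = 4 each, adjusted p = 0.830). Without non-exposed mouse 3 and HFD-exposed mouse 4, 73.9% of their mean difference was left (1.05 with 8 mice and 0.78 without, with no overlap), which argues against these mice as the whole cause. A candidate explanation is that reads of ribosomal RNA were counted to genes that hold a copy of its sequence. The 5 other such genes, AY036118, Lars2, Cdk8, Camk1d and Gm15564, had a median log2 fold change of 0.71 with values from 0.36 to 0.97, which is consistent with it, although their score differed by 0.55 with an exact permutation p of 0.2. An effect of diet on the amount of ribosomal RNA captured stays open and untested.

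The 8 mice can be split into 4 and 4 in 35 ways, and chance could not be excluded for any count of called genes or lists above 0. Each number of splits given below includes the split by diet itself. As many genes as between the diets were called in 4 splits for GMP-like cells (3 genes, highest other split 124), 3 for HSC/MPP-like cells (5, 68), 3 for monocyte progenitor-like cells (5, 50) and 3 for megakaryocyte-like cells (2, 349). The same held in 5 splits for T, NK and innate lymphoid-like cells (2 genes, highest other 30), 6 for basophil and mast-like cells (2, 23), 7 for cluster 11 (1, 56), 4 for late erythroid-like cells (1, 193) and 12 for plasma cell-like cells (1, 2). For all cells, erythroid progenitor-like cells and the difference between classes, each with 0 genes between the diets, all 35 splits gave as many by construction, which says nothing of chance, and the highest others were 6325, 599 and 243. Splits with several times the count between the diets point to a structure of the samples that does not follow the diets exactly. For all cells the split with 6325 genes set non-exposed mice 1 and 2 and HFD-exposed mice 2 and 3 against the rest. Late erythroid-like cells made up 6.01%, 8.34%, 7.41% and 8.87% of the kept cells in these 4 mice, in that order. In the others they made up 17.6% to 22.8%. Whether this share gives rise to the structure was not tested. In GMP-like, HSC/MPP-like, basophil and mast-like, cluster 11, megakaryocyte-like, monocyte progenitor-like and both erythroid classes, 1 split gave the highest count. It set non-exposed mice 1, 2 and 3 and HFD-exposed mouse 2 against the rest. This split keeps most mice of each diet together, but many of the 35 splits do so. It therefore does not show whether any of the structure follows the diet. As many lists were called in 25 splits for all cells (7 lists, highest other 19), 10 for GMP-like (8, 12), 24 for HSC/MPP-like (5, 11), 17 for T, NK and innate lymphoid-like (4, 7), 16 for basophil and mast-like (5, 10) and 12 for cluster 11 cells (5, 9). The numbers were 20 for erythroid progenitor-like (7, 14), 11 for late erythroid-like (7, 12), 19 for megakaryocyte-like (6, 10), 22 for monocyte progenitor-like (5, 9) and 25 for plasma cell-like cells (3, 10). An example of this structure is Tspoap1, a gene for a protein that binds the benzodiazepine receptor of mitochondria, at 219, 164, 107 and 9.81 CPM in erythroid progenitor-like cells of non-exposed mice 1 to 4 and at 13.3, 59.9, 34.5 and 18.0 CPM in HFD-exposed mice 1 to 4.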
